A study of Mus musculus with 6 samples.

How the data were processed

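The samples were hypertrophic zones of the proximal tibial growth plate of 7-day-old C57BL/6 mice, 3 wild type (WT) and 3 homozygous for a loss of Adamts17, described as littermates by the labels. Per the labels' protocols, bones were flash frozen and cryosectioned, the zone was cut out by laser microdissection, RNA was isolated with a PicoPure kit, messenger RNA was linearly amplified with RiboAmp HS PLUS, and libraries were made with the Illumina TruSeq RNA kit, version 2. Whether each library came from a separate animal is not stated beyond the word littermates, so p-values measure the spread between these libraries.

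The authors deposited 1 table with a value for each of 14882 genes in each of the 6 libraries, with gene coordinates, transcript length and pathway names. No source used here names the unit. The deposited values were read as RPKM, because each library's value times transcript length fell on multiples of 1 step, and on simple fractions of it, down to 1 part in 20. The deposited table's name says that it was scaled by trimmed means of M-values (TMM). The aligner, the counting program, the genome build and the handling of reads with several positions are not given in the sources used here. Dividing by the step gave read equivalents. Between 24.0% and 34.4% of values from 1 to 20 read equivalents were whole within 0.01, so these are not whole reads and no count model was fitted. Of 13903 gene symbols found on the same chromosome in the RefSeq annotation of GRCm38.p6, 89.9% had a start within 1000 bp of the table's, so coordinates below are the table's own and were not converted.

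Groups and replicate numbers came from the sample titles, and columns were matched to samples by the sample descriptions. No pair of libraries shared an equal value above 0 for any gene. Values were analysed as log2(RPKM + 1), for genes with a value of at least 1 in at least 3 libraries (9128 genes). A fold change on this scale understates that of low genes. The WT and Adamts17-/- libraries were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. A list needed at least 3 tested members. Exact permutation tests of list means, two-sided, cannot go below 0.1 with 3 libraries against 3. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, searches of the transcript sequences and plots.

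The test, the 24 gene lists, the naming of genes and the alternatives were fixed before the data were examined, except where said. The naming rule took Adamts17, up to 10 called genes per direction (filled to 5 by the smallest p where fewer were called, among genes with no overlap between groups and a mean of at least 5 in the higher group), 25 fixed genes, and up to 2 members per direction of each list. Of 499 list entries, 439 were matched to rows of the table, older symbols through RefSeq synonyms. The list of mitochondrial transcripts had 0 rows in the table and was not analysed here. The test was checked on simulated data with the real gene levels and spread (5 simulations of 9128 genes, with 50 genes changed per fold size). It recovered 0.8% of genes changed 4-fold, 12.8% at 16-fold, 58.8% at 64-fold and 88.4% at 256-fold, with a mean of 2.4 false calls. Changed genes were drawn only from genes with a higher mean level. Simulated values could also fall below 0, which log2(RPKM + 1) cannot. Recovery at large folds may therefore be overstated for the real data. For lists shifted by -1.50 on the log2 scale, camera called 14 of 20 at the preset correlation and 0 with an estimated one. Among unshifted lists it called 3 of 419 and 0. The simulated genes varied independently, while the estimated correlation was 0.19 in the cartilage matrix list and 0.84 in the erythroid list. False calls at the preset correlation may therefore be more frequent in the real lists. The alternatives tried were other pseudocounts, filters, scalings, spread models, library weights, a replicate block and each library left out. Alternatives chosen after seeing the data were voom on the read equivalents, both doubted libraries left out, and the genes locked in ratio to Fndc9 left out.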

Results

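Gene expression was measured in the hypertrophic zone of the proximal tibial growth plate, the layer of enlarged chondrocytes at which cartilage mineralises and is replaced by bone, in 3 WT and 3 Adamts17-/- libraries from mice aged 7 days. Adamts17 encodes a secreted metalloprotease of the ADAMTS family. The comparison asks which genes of the hypertrophic zone differ when it is missing. The libraries were shallow and uneven. Read equivalents on listed genes numbered 1662637, 722119 and 899162 in WT replicates 1, 2 and 3, and 882809, 2688295 and 595989 in Adamts17-/- replicates 1, 2 and 3. Genes listed at 0 numbered 391, 2476 and 3108 in WT and 2280, 2112 and 3153 in Adamts17-/-. Of 4179 genes with a mean of at least 50 read equivalents, 1692 (40.5%) had at most 1 in some library. Across genes, Pearson's r between libraries averaged 0.480 between groups, 0.459 within WT and 0.416 within Adamts17-/-. A single gene, Fndc9, took 2.26%, 5.50% and 19.1% of read equivalents in WT and 5.92%, 4.50% and 15.4% in Adamts17-/-.

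**Figure D1:**
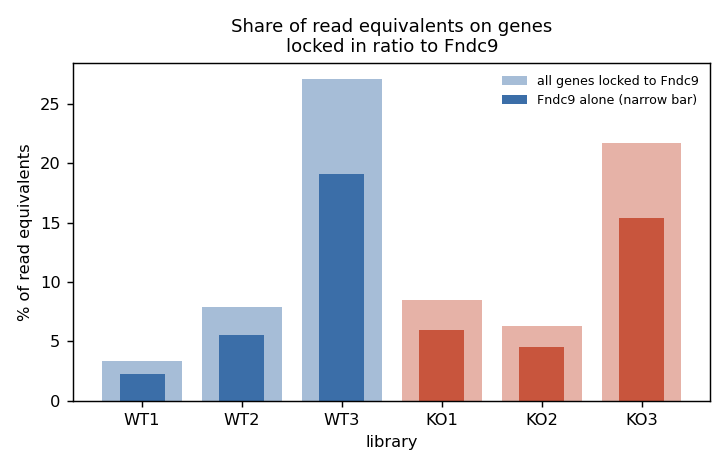
Share of read equivalents, in percent, in each of the 6 libraries, on Fndc9 alone (narrow bars) and on the 47 genes with a nearly fixed ratio to it, Fndc9 included (wide bars). The share of the 47 genes ran from 3.34% in WT replicate 1 to 27.1% in WT replicate 3, and from 6.31% to 21.7% in Adamts17-/-.

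Adamts17 itself (Entrez gene 233332, chromosome 7, 66839735 to 67152625, transcript length 6029 bp) was near the floor in all libraries. Its RPKM was 0.246, 0.0407 and 0.397 in WT replicates 1, 2 and 3, and 0.0085, 0.0870 and 0.0260 in Adamts17-/-. These are 6.49 read equivalents summed over WT and 1.25 over Adamts17-/-. The gene fell under the filter, and in the fit without a filter its log2 fold change was -0.23 ± 0.26 (SE, n = 3 per group, limma adjusted p = 0.99996). The targeted gene therefore could not check the labels at this depth, and the part of the gene that was deleted is not given in the sources used here.

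Genes of cartilage matrix and early chondrocytes were lower together in the Adamts17-/- libraries, with 17 of 18 tested members lower. The list's mean log2(RPKM + 1) was 5.87 ± 0.66 in WT and 4.22 ± 0.54 in Adamts17-/- (SD, n = 3), and all 3 Adamts17-/- libraries lay below all 3 WT libraries (exact permutation p = 0.1, the smallest possible). The list was called by camera at the preset correlation (adjusted p = 4.76e-07), and with an estimated correlation the adjusted p was 0.470. The estimated form called 0 of 20 simulated shifted lists, so its adjusted p-values here and below cannot show that a difference is absent. Fmod, a small matrix proteoglycan, was at 35.0, 32.1 and 3.27 RPKM in WT and 0, 0 and 0.137 in Adamts17-/- (log2 fold change -4.04 ± 1.498, SE). Lect1, the chondromodulin gene, was at 49.7, 113 and 56.9 in WT and listed at 0, 0 and 63.3 in Adamts17-/- (-4.12 ± 1.58). Col2a1, the main cartilage collagen, had a log2 fold change of -1.41 ± 1.05, and Acan, the aggrecan core protein, -1.005 ± 1.17. With 1 library left out, Col2a1 ran from -1.95 to -0.86 and Acan from -1.62 to -0.36. Wif1, the single member that was higher, was at 0.61 ± 1.53. None of the members passed the test over all genes or adjusted over the list alone.

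Genes of the hypertrophic state were divided. Of 15 tested hypertrophic chondrocyte markers 7 were higher and 8 lower, and the list was not called (camera adjusted p = 0.117). It was called lower with quantile normalization of all 6 libraries (mean log2 difference -0.71, camera adjusted p = 0.0107, and adjusted p = 0.315 with an estimated correlation) and without WT replicate 1 (-0.76, camera adjusted p = 0.0293, and adjusted p = 0.561 with an estimated correlation). Without both WT replicate 1 and Adamts17-/- replicate 2 it was also called lower (-1.11, camera adjusted p = 0.0373, and adjusted p = 0.642 with an estimated correlation). The mean log2 difference was -0.49 with all 6 libraries. With 1 library left out it ran from -0.85 (without Adamts17-/- replicate 2) to -0.051 (without Adamts17-/- replicate 3), and was -0.11 without WT replicate 3. Col10a1, the collagen specific to hypertrophic cartilage, was at 2218, 13347 and 5866 RPKM in WT and 1437, 1507 and 4151 in Adamts17-/- (log2 fold change -1.42 ± 0.88). Mmp13, a collagenase of the late hypertrophic zone, was at 1150, 40.9 and 1861 in WT and 71.2, 424 and 36.6 in Adamts17-/- (-2.09 ± 1.28). Spp1, which encodes osteopontin, was at -1.31 ± 1.12, Alpl at 0.55 ± 1.25 and Ibsp at 1.21 ± 1.35. Leaving out WT replicate 1 moved the log2 fold change of Alpl to -0.70, and leaving out Adamts17-/- replicate 2 moved that of Ibsp to -0.23. Ihh, the signal of prehypertrophic cells, was at 0.11 ± 1.53 and Pth1r, the receptor of parathyroid hormone-related protein, at -0.08 ± 0.97. Among mineralisation genes 5 were higher and 11 lower (camera adjusted p = 0.117), and this list too was called lower with quantile normalization (-0.80, and adjusted p = 0.315 with an estimated correlation).

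**Figure D2:**
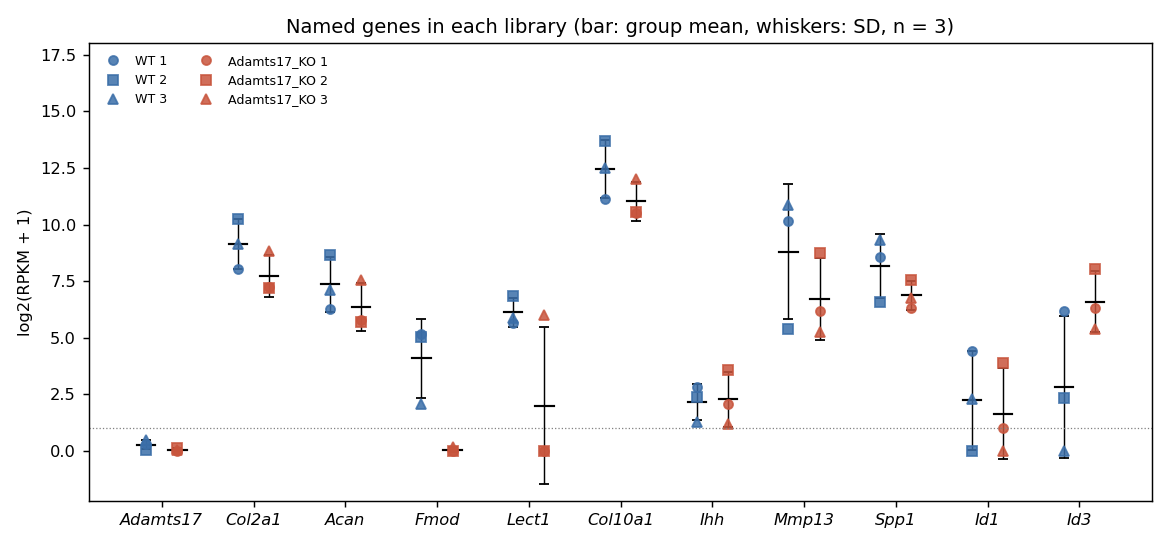
Level of 11 named genes in each library as log2(RPKM + 1), with 3 WT and 3 Adamts17-/- libraries. Points are libraries, bars group means and whiskers SD, and the dotted line marks an RPKM of 1. Adamts17 lies under that line in all 6 libraries, Fmod lies under it in the 3 Adamts17-/- libraries, and the groups overlap for Col2a1, Acan and Col10a1.

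Targets and components of BMP signalling gave no list call. Of 13 tested BMP-SMAD targets 6 were higher and 7 lower (camera adjusted p = 0.663). Id3, an immediate target of BMP signalling, was at 72.3, 4.01 and 0 RPKM in WT and 79.7, 263 and 41.1 in Adamts17-/- (log2 fold change 3.75 ± 1.502, limma unadjusted p = 0.0180, adjusted p = 0.999). Id1 was at -0.59 ± 1.52 and Id2 at 0.19 ± 1.70. With upper-quartile scaling the sign turned for Id2 (-0.075), Ihh (-0.16) and Runx2 (-0.053, against 0.21 ± 1.32), a scaling that moved the median of all genes by -0.22. Among BMP ligands, receptors and modulators 4 were higher and 9 lower (camera adjusted p = 0.145). Without Adamts17-/- replicate 3 that list was called lower (mean log2 difference -0.86, adjusted p = 0.0319, and adjusted p = 0.507 with an estimated correlation). Of the fibrillin microfibril list, which holds fibrillins and proteins associated with microfibrils or elastic fibres, 4 tested genes were higher and 9 lower (camera adjusted p = 0.117). That list's mean was 3.50, 2.79 and 3.28 in WT and 2.41, 2.64 and 2.73 in Adamts17-/-, so all 3 Adamts17-/- libraries lay below all 3 WT libraries (exact permutation p = 0.1, the smallest possible). Of the 23 lists tested, the cartilage, fibrillin and ADAMTS lists were separated in this way, where chance gives 10% of lists. Without a filter on low values it was called lower (mean log2 difference -0.73, camera adjusted p = 0.0243, and adjusted p = 0.522 with an estimated correlation). Fbn1 was at -1.497 ± 1.45, Fbn2 at -0.86 ± 0.89 and Ltbp1 at 0.72 ± 1.60. With 1 library left out, Fbn1 ran from -2.16 to -1.01 and Fbn2 from -1.58 to -0.037. Of the 25 fixed genes 20 were tested, 7 were higher and 13 lower, and none passed the test over all genes or adjusted over the list alone.

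The ADAMTS family list was lower in Adamts17-/-, with 5 of 7 tested members lower. Its mean was 2.72 ± 0.75 in WT and 1.68 ± 0.05 in Adamts17-/- (camera adjusted p = 0.0389, and adjusted p = 0.470 with an estimated correlation). All 3 Adamts17-/- libraries lay below all 3 WT libraries (exact permutation p = 0.1, the smallest possible). Adamts14, a procollagen peptidase, had a log2 fold change of -2.29 ± 1.02, and Adamts5, an aggrecanase, -2.26 ± 1.33. Both were low: Adamts14 was at 3.98, 1.09 and 14.6 RPKM in WT and 0.0625, 0 and 0.317 in Adamts17-/-. Adamts5 was at 4.69, 1.25 and 28.5 RPKM in WT and 2.11, 0.0184 and 0.0838 in Adamts17-/-. Adamts3 was at 1.27 ± 1.62, and ran from 0.069 to 2.29 with 1 library left out. The call was lost in 10 of 21 alternatives, among them a pseudocount of 0.1, no filter, quantile normalization, no intensity trend and library weights. These include 4 of the 6 fits that left out 1 library, with a mean log2 difference of -0.61 without WT replicate 3, -1.02 without Adamts17-/- replicate 3, -1.04 without replicate 1 and -1.07 without replicate 2.

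Markers of other tissues differed between single libraries more than between groups. Skeletal muscle genes were lower in Adamts17-/-, with 13 of 13 tested members lower (camera adjusted p = 3.98e-07, and adjusted p = 0.470 with an estimated correlation). The list mean was 8.47, 4.98 and 2.08 in WT replicates 1, 2 and 3, and 4.07, 3.07 and 1.56 in Adamts17-/-. Myl1, a fast muscle myosin light chain, was at 3596 RPKM in WT replicate 1 and between 0 and 133 in the other libraries, and was the 1 gene called when adjusted over the list alone. Without WT replicate 1 the mean difference was -0.63 and the list was no longer called (adjusted p = 0.146). Erythroid genes were higher, with 10 of 10 members higher (camera adjusted p = 0.000116, and adjusted p = 0.470 with an estimated correlation). The list holds several globin genes and its members varied together (estimated correlation 0.84), so these are not 10 separate observations. Hba-a1, an alpha globin, reached 68434 RPKM in Adamts17-/- replicate 2, against 16922 in WT replicate 2 and 821 in WT replicate 1. Myeloid genes were higher for 12 of 17 members (camera adjusted p = 0.0389, and adjusted p = 0.584 with an estimated correlation). S100a8, a neutrophil calcium-binding protein, was at 20184 RPKM in Adamts17-/- replicate 2 and at most 597 elsewhere. Without that library the mean difference was 0.12 for erythroid genes and -0.64 for myeloid genes, and neither list was called (adjusted p = 0.851 and 0.290). The erythroid call was also lost without WT replicate 1 (1.40, adjusted p = 0.129) or 3 (1.27, 0.0583), and the myeloid call without WT replicate 2 (0.73, 0.0968) or 3 (0.39, 0.487). The myeloid list was also not called with pseudocounts of 0.1 (adjusted p = 0.177) or 0.5 (0.0981), a minimum value of 5 (0.17003), quantile normalization (0.0963), no intensity trend (0.108) or voom (0.0748). With library weights it was called in the opposite direction, lower in Adamts17-/- (mean log2 difference -1.27, camera adjusted p = 0.0362, and adjusted p = 0.550 with an estimated correlation).

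Genes of the cell cycle were higher in Adamts17-/-, with 20 of 21 members higher (camera adjusted p = 7.52e-05, and adjusted p = 0.470 with an estimated correlation). The list mean was 2.89 ± 0.37 in WT and 4.35 ± 1.47 in Adamts17-/-, with the highest value, 5.94, in replicate 2, which also had the highest erythroid and myeloid means. Pcna, the sliding clamp of DNA replication, was at 1042 RPKM in that library and between 10.1 and 220 in the others. Without it the mean difference was 0.66 and the list was no longer called (adjusted p = 0.107).

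**Figure D3:**
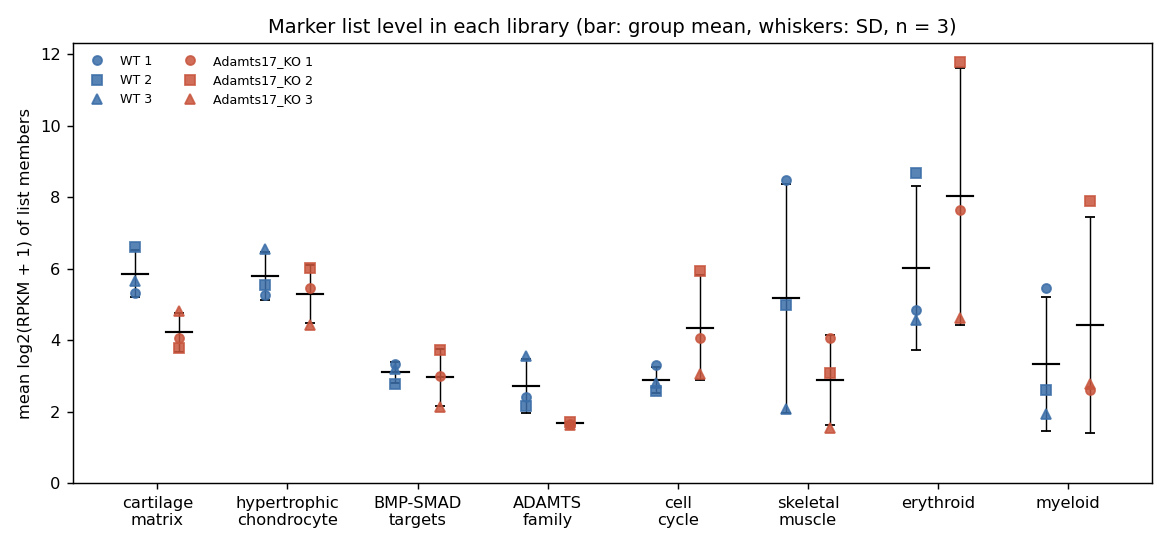
Mean log2(RPKM + 1) of the tested members of 8 marker lists in each library, with 3 WT and 3 Adamts17-/- libraries. Points are libraries, bars group means and whiskers SD. The cartilage matrix list lies lower in all 3 Adamts17-/- libraries, the muscle list is highest in WT replicate 1 (8.47), and the erythroid and myeloid lists are highest in Adamts17-/- replicate 2 (11.8 and 7.90).

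The remaining lists were not called in the planned fit. Members higher and lower numbered 5 and 7 for TGF-beta targets (camera adjusted p = 0.463), 7 and 7 for matrix metalloproteases and their inhibitors (0.497), 0 and 4 for hedgehog targets (0.117), 8 and 6 for the WNT pathway (0.663) and 4 and 10 for the IGF and growth hormone axis (0.117). They numbered 10 and 11 for the unfolded protein response (0.123), 10 and 13 for hypoxia and glycolysis (0.509) and 7 and 5 for immediate early and stress genes (0.324). For cell types they numbered 5 and 7 for osteoblasts and osteocytes (0.663), 2 and 9 for osteoclasts (0.117), 4 and 14 for endothelium (0.117) and 2 and 9 for perichondrium and fibroblasts (0.0918). Without WT replicate 2 the osteoclast (mean log2 difference -1.55), perichondrium (-1.503), endothelial (-1.09), IGF (-0.99) and unfolded protein response (-0.82) lists were called lower, each with an adjusted p of 0.403 with an estimated correlation. Without WT replicate 1 the same lists were at -0.08, -0.13, 0.05, -0.37 and -0.36, and none of them was called. The perichondrium list was also called lower without Adamts17-/- replicate 2 (-1.64, adjusted p = 0.520 with an estimated correlation) and the osteoclast list without replicate 3 (-1.13, adjusted p = 0.598 likewise). With all 6 libraries, library weights called the perichondrium (-2.22), osteoclast (-1.73), endothelial (-1.36), metalloprotease (-1.07) and unfolded protein response (-0.92) lists lower, each with an adjusted p of 0.397 with an estimated correlation. The metalloprotease list was at -0.18 in the planned fit. With 1 library left out it ran from -0.64 (without Adamts17-/- replicate 2) to 0.31 (without WT replicate 1). Quantile normalization called the perichondrium (-0.997, adjusted p = 0.315 with an estimated correlation) and osteoclast lists (-0.90, adjusted p = 0.364 likewise). The median and mean differed in sign for the WNT list (0.17 and -0.08) and the osteoblast list (-0.16 and 0.24).

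Over all 9128 genes, 0 were called higher and 0 lower in Adamts17-/- by limma at an adjusted p under 0.05, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 229 genes, 104 higher and 125 lower, where chance gives 456.4. By voom on the read equivalents 0 genes were called and 446 had an unadjusted p under 0.05. Genes with no overlap between groups numbered 605 (6.63%), where chance gives 10%. The genes with the smallest p among these, none of which passed, were Timm23, Siva1, Urod, Tma16 and Eif6 on the higher side and Uck2, Myl1, Tceal7, Car10 and Ankrd1 on the lower side. Timm23, a mitochondrial import protein, had a log2 fold change of 5.66 ± 1.502, with 66.3, 0 and 0 RPKM in WT and 167, 171 and 301 in Adamts17-/-. Uck2, a uridine-cytidine kinase, was at -5.61 ± 1.60, with 10.99, 82.8 and 157 in WT and 0.364, 0 and 0 in Adamts17-/-. The median SE of a log2 fold change was 1.48. Without Adamts17-/- replicate 3, 5 genes were called higher: the neutrophil gene S100a9 and Stfa1, Stfa3, BC100530 and Gm5483, named here after their values were seen.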

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

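The fits with voom, without WT replicate 1 and Adamts17-/- replicate 2 together, and without the genes locked to Fndc9 were chosen after seeing the data. The 22 alternative gene fits gave 135 to 799 genes at an unadjusted p under 0.05, and 20 of them called 0 genes. Library weights called 1 gene lower (Myl1, adjusted p = 0.00451), and leaving out 1 library gave 0 to 5 genes called higher (5 without Adamts17-/- replicate 3) and 0 lower. With the titles' numbers as a replicate block, 0 genes were called higher, 0 lower and 6 lists were called. Same-numbered libraries deviated with correlations of -0.01, -0.35 and -0.10, and differently numbered ones between groups with -0.17 to 0.22. Pairing by number was thus not seen, but so few libraries cannot exclude it. The log2 fold change of Adamts17 stayed below 0 (-1.08 to -0.065, and -0.34 to -0.13 with 1 library left out), and a minimum value of 5 gave it no value. The 6 lists called became 10 with library weights and 2 without WT replicate 1 and Adamts17-/- replicate 2 (cartilage matrix and hypertrophic). They became 0 with an estimated correlation, 0 with fry, and 3 to 10 with 1 library left out. In simulation the estimated correlation called 0 of 20 shifted lists, and fry was not tried, so these 0 calls cannot exclude a difference. The cartilage list kept its direction and its camera call at the preset correlation in all 22 refits (mean log2 difference -2.07 to -1.28, adjusted p at most 0.00396). Upper-quartile scaling moved the median log2 fold change of all genes by -0.22, and totals without the top 10 genes moved it by -0.18. Of 47 named genes, 1023 values under alternatives held 56 changes of sign, in 18 genes, all with a main log2 fold change that had not passed. Id2 moved to -0.75 and -0.056 with pseudocounts of 0.1 and 0.5, and Mcm4 to 0.12 with 4 and 0.55 with voom. Quantile normalization gave Ihh -0.014, Runx2 -0.0084, Id2 -0.11 and Gdf5 0.16. Upper-quartile scaling gave Ihh -0.16, Runx2 -0.053 and Id2 -0.075, and totals without the top 10 genes gave -0.11, -0.0065 and -0.047. Library weights gave Ihh -0.55, Vegfa 0.30, Pth1r 0.78, Id2 -0.70 and the myeloid list -1.27, a call in the opposite direction (adjusted p = 0.0362). Without WT replicate 1 and Adamts17-/- replicate 2 the values were Ihh -0.21, Alpl -0.94, Ibsp -1.29, Vegfa 0.48, Pth1r 0.19, Sox9 0.40, Id2 -1.39, Gdf5 0.25, Adamtsl4 -0.023, Hba-a1 -0.64, Csf1r 0.77 and the erythroid list -0.48. With 1 library left out, values ran from -1.88 to 2.33 for Id2, -1.48 to 0.84 for Mcm4, -0.54 to 0.65 for Ihh, -0.22 to 0.72 for Runx2, -1.46 to 0.30 for Gdf5, -1.05 to 0.67 for Vegfa, -0.47 to 0.58 for Pth1r, -0.18 to 0.70 for Adamtsl4, -2.07 to 0.13 for Csf1r, -0.70 to 1.497 for Alpl, -0.23 to 3.07 for Ibsp, -2.73 to 0.76 for Cd68, -1.72 to 0.50 for Id1, -0.25 to 1.61 for Wif1, -0.15 to 1.40 for Ltbp1, -1.72 to 0.052 for Bmp2 and -0.64 to 2.16 for the myeloid list. The cause was not tested. Count models on whole reads were not run, because the read equivalents were mostly not whole. Simulated 4-fold changes, in genes with a higher mean level and at the real spread, were recovered at 0.8%, and depth was not varied apart from spread.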

Other observations

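The tests in this part were chosen after the results were seen, except that of cartilage genes against matched random lists, fixed before its result. Among 242 pathways named in the deposited table with at least 10 tested genes, camera called 7 at the preset correlation, all higher in Adamts17-/-, and 0 with an estimated correlation (smallest adjusted p = 0.981). Ribosome genes were higher for 108 of 126 members (mean log2 difference 0.69) and DNA replication genes for 25 of 28 (1.55). The others were the systemic lupus erythematosus pathway, which lists many histone genes, and those of porphyrin metabolism, mismatch repair, base excision repair and the cell cycle. Without Adamts17-/- replicate 2, 0 of the 242 pathways were called, and all 7 differences were smaller but still above 0. They went from 0.69 to 0.18 for the ribosome, 1.55 to 0.65 for DNA replication, 0.96 to 0.62 for lupus, 1.41 to 0.90 for porphyrin metabolism, 1.46 to 0.46 for mismatch repair, 1.18 to 0.72 for base excision repair and 0.66 to 0.12 for the cell cycle.

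Y-linked transcripts were lower in Adamts17-/-, and the labels give no sex. The summed read equivalents of 4 Y-linked genes were 416, 48.4 and 285 in WT replicates 1, 2 and 3 and 30.1, 0.767 and 2.17 in Adamts17-/-, so every WT library was above every Adamts17-/- library (exact permutation p = 0.1, the smallest that 3 against 3 allows). These sums were not scaled for depth. In RPKM, Ddx3y was at 17.5, 0.627 and 18.2 in WT and 1.70, 0.0394 and 0.394 in Adamts17-/-. Kdm5d was at 5.06, 8.37 and 0.189 RPKM in WT and 3.91, 0.0334 and 0.287 in Adamts17-/-. Both genes were higher in Adamts17-/- replicate 1 than in replicates 2 and 3, so Y-linked signal also differed within Adamts17-/-. Sex was not separated from genotype here, how far it followed genotype was not settled, and no fit held a term for it. By gene, read equivalents of Eif2s3y were 67.1, 4.11 and 212 in WT replicates 1, 2 and 3 and 0 in all 3 Adamts17-/- libraries. Ddx3y was at 232, 2.28 and 72.3 in WT and 8.10, 0.383 and 1.17 in Adamts17-/-, and Uty at 38.1, 6 and 0 in WT and 0 in all 3 Adamts17-/- libraries. Kdm5d was at 79.0, 36.0 and 0.883 in WT and 22.0, 0.383 and 1 in Adamts17-/-. Xist, the RNA of the inactive X, was at 114, 6.82 and 17.2 in WT and 7.40, 80.5 and 181 in Adamts17-/-.

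The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. All splits but the real one hold both genotypes on each side in unequal numbers, so they carry part of any genotype difference. Genes at a limma unadjusted p under 0.05 numbered 229 in the real split, fewer than in any other split (242 to 1187). The real split called 0 genes, and all 10 splits called as many, with at most 2 in another split. It called 6 lists, the highest of the other splits called 4, and 1 split, the real one, gave as many as 6. For the cartilage list the mean log2 difference was 1.64 in size (limma camera adjusted p = 4.76e-07) in the real split. It was 1.30 (adjusted p = 5.34e-06) when WT replicate 1 was grouped with Adamts17-/- replicates 1 and 2, and camera at the preset correlation also called the list in the splits that grouped WT replicates 1 and 2 with Adamts17-/- replicate 3 (1.08, adjusted p = 0.00823) and WT replicate 1 with Adamts17-/- replicates 2 and 3 (0.805, adjusted p = 0.0111).

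The cartilage matrix list was lower in all 3 Adamts17-/- libraries. Dilution by blood in replicate 2 alone is argued against, since without that library the difference was -1.42 ± 0.53 (SE over libraries). The erythroid difference was then 0.12 ± 2.003 (SE over libraries). That spread is too wide to show equal blood content in the remaining libraries, so dilution by blood in those is not excluded. Loss of transcripts by gene level and length was not decided by 10000 random lists matched on both. The share with a mean as low was 0.0001, the smallest these draws can give, and their lowest mean was -0.99. Their members were drawn independently, while members of a real list vary together more than random genes. Splits that mixed the genotypes also moved the cartilage list further than that in size (1.30 and 1.08). Such splits still hold unequal numbers of each genotype on their sides, so they carry part of any genotype difference. Because the random lists lack the joint variation of a real list, this test cannot decide. A dissection with fewer cells from the proliferative side in Adamts17-/- stays open, because the cell cycle list, which such a shift should lower, was at 0.66 ± 0.55 without replicate 2 and marrow cells also cycle. A difference in sex between the groups is not excluded for this list, since Y-linked reads were also higher in every WT library. An effect of the genotype on cartilage matrix genes is a hypothesis that may be followed up with more animals of known sex.

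The muscle, erythroid and myeloid differences moved widely with single libraries, from -3.83 (without WT replicate 3) to -0.63 for muscle, 0.12 to 3.69 (without Adamts17-/- replicate 3) for erythroid and -0.64 to 2.16 (without WT replicate 1) for myeloid genes. Muscle RNA in WT replicate 1 is a candidate source of the muscle difference, which was -2.28 with all libraries and -0.63 without that one. Blood in Adamts17-/- replicate 2 could account for the erythroid difference (0.12 without it), and marrow for the myeloid difference (-0.64 without it). Genotype was not shown to be needed for any of these 3 lists, and muscle, vessels and marrow lie close to the dissected zone.

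Fndc9 and 46 other genes, among them Hdac3, Camk2b and Lca5, kept a nearly fixed ratio in all 6 libraries (SD of the ln ratio to Fndc9 under 0.15, of 2602 genes compared), with Fndc9 to Hdac3 between 6.97 and 8.20 while Fndc9 itself varied 4.59-fold. Reads shared through common sequence are argued against: 0 of 44 genes shared a 25-base word with Fndc9, against 29 members of a second locked set with their anchor Slfn5. Primer sequence of the T7-based amplification may be the source: of all 186489 10-base words compared, the one most enriched was part of the T7 promoter, in 10 of 45 locked genes against 0.521% of other genes. That word was found by this search, and in the 74 less tightly locked genes kept out of it 2 held the word, with a share of 0.0459 of length-matched draws giving as many, so these genes are too few to decide. The share of reads on the locked set was 12.8% ± 12.6 in WT and 12.2% ± 8.3 in Adamts17-/- (SD, n = 3, exact permutation p = 0.9), and no biological explanation was tested.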
